A study of Solenopsis invicta with 4 samples.

How the data were processed

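Total RNA from brains of adult female workers of the fire ant Solenopsis invicta, from colonies of the polygyne social form in which several queens reproduce, was sequenced in 4 samples titled Worker 1 to Worker 4. Per the labels' protocols, brains were dissected in cold buffered saline and frozen on dry ice, RNA was taken with Trizol, and libraries were made from total RNA with a strand-marking Illumina TruSeq kit. Bcl2fastq 2.17.1.14 is the tool named in the submitters' processing notes. The labels describe all 4 samples in the same words and name no condition, although the series' design text speaks of 3 replicates per condition. The 4 samples were therefore left without a group, each is reported by its own value, and no test across samples was made.

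Each deposited file lists the transcripts of 1 sample as assembled by Cufflinks, which is named on every line. Per the files, the assembly was guided by a RefSeq annotation: annotated transcripts, with gene and transcript accessions, stand beside assembled transcripts that carry Cufflinks's own numbers. The aligner, the Cufflinks version and settings and the name of the genome build are not given in the sources used here. Scaffold names start with Si_gnG, a mitochondrial sequence is named MT, and all coordinates are those of the files, counted from 1. Each transcript has a deposited FPKM value (fragments per kilobase of transcript, scaled to the number of mapped fragments), a lower and an upper confidence bound, a coverage and a mark that says whether reads supported the whole transcript. Coverage divided by FPKM was a single constant in each file, so coverage held nothing further. Between 94.0% and 95.3% of the assembled transcripts with 1 exon carried no strand, so sense and antisense transcription of unspliced loci cannot be separated in these files although the kit marks strand.

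Depth was worked out from the bounds. For a transcript alone in its Cufflinks gene, the upper bound exceeded the FPKM by 2 times the FPKM over the square root of a fragment number, and that number was whole within 0.05 for between 71.0% and 72.6% of the values under 20.5 fragments. A Theil-Sen line of fragments per unit FPKM against transcript length, over transcripts of 1000 to 6000 nt with at least 100 fragments, gave the number of mapped fragments as its slope. The slope was 33966957 for Worker 1, 34858348 for Worker 2, 34001438 for Worker 3 and 35787472 for Worker 4. At such depths the authors' bounds are narrow for most loci, and they cover counting error and the division of reads among isoforms, not differences between samples or library preparations. Over these transcripts the line also showed that between 334 and 361 nt were taken off the length, as a correction for fragment length would do. Less was taken off shorter transcripts, since some of 125 nt still have an FPKM value.

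The files list 22755 reference transcripts. Of their 22064 RefSeq accessions 10852 were found in a RefSeq gene table of assembly UNIL_Sinv_3.0, which is not the files' build and was used for names and gene types alone. A gene identifier came from the files for 8851 transcripts and from that table for 7442, and 6462 kept their own identifier. Reference transcripts that shared a gene identifier or overlapped by exons on 1 strand were joined, which gave 15589 annotated loci, 42 of them with more than 1 gene identifier and 2886 nuclear loci with none, named here by a transcript. Of 12556 gene identifiers 9743 were in the table. On the mitochondrial sequence every entry was kept as a locus of its own. The level of a locus is the sum of the FPKM of its reference transcripts and of assembled transcripts that counted for it. An assembled transcript counted for each locus of its Cufflinks gene with a reference transcript it covered by at least 50%. An assembled transcript that covered none to that extent counted for the locus with which it shared the most bases, however few. Assembled transcripts from Cufflinks genes without any reference transcript are called unannotated, and were joined across samples by exon overlap on compatible strands.

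A locus counted as detected at 1 FPKM or more. Similarity was computed across loci with a mean level of at least 1 on log2(FPKM + 1), as Pearson and Spearman correlations for the 6 pairs of samples. Loci are not independent replicates, so these correlations carry no p-value. Variation was counted as loci whose highest sample was at least 2 or at least 4 times the lowest after adding 1 FPKM to each, and such ratios understate differences of weakly expressed loci. The rule for named genes, fixed before the data were examined together with the thresholds above, takes the 20 loci with the highest median level, the 10 with the largest ratio among loci of mean level 5 or more, and for each sample the 5 such loci in which it lies farthest from the nearest of the other samples. Loci called ribosomal RNA or tRNA were left out of it. The 22 gene lists fixed at the same time select by product description. Neither the files nor the table used here pair identifiers with descriptions, so list levels and list shifts per sample were not computed. Genes with a name of their own in the table, the mitochondrial genes and the assembled transcripts given by position were chosen after the data were examined.

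The counts were repeated with other detection thresholds (0.1 and 5 FPKM), with TPM scaling, with the most abundant transcript of each locus, with median-of-ratios size factors, with another pseudocount, with other filters on low values and without each sample in turn. After the data were examined, further choices were added: the mean depth over a locus's reference exons from all transcripts that overlap them, reference transcripts alone, transcripts of at least 200 nt, and counts without loci listed at 0 or with the transcript length trend removed. The computations were done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The code was tested on simulated data. The simulated levels had counting noise alone, and only loci with a mean of at least 5 FPKM were scored. In 10000 simulated loci, 100% of scored loci changed 3-fold were found at the 2-fold limit and 100% of those changed 6-fold at the 4-fold limit. Of unchanged loci 0% were found at the 2-fold limit. These shares check the code and are not error rates of the counts reported here, which start at a mean of 1 FPKM. The simulated depth was recovered from 4000 other simulated loci.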

Results

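Brain transcriptomes of adult female fire ant workers of the polygyne form were available in 4 samples as transcript assemblies with FPKM values. The labels do not say how many ants each sample holds, and give no treatment, age class or colony that would divide them, so every value is given per sample, and differences between samples are described without a test. The files imply 33966957 mapped fragments in Worker 1, 34858348 in Worker 2, 34001438 in Worker 3 and 35787472 in Worker 4, so the deepest sample held only slightly more fragments than the shallowest. Each file listed between 38088 and 38702 transcripts, of which between 15333 and 15950 were assembled ones outside the RefSeq models.

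Most annotated loci were transcribed in these samples. Of 15589 annotated loci, 10007 reached 1 FPKM in Worker 1, 10077 in Worker 2, 10149 in Worker 3 and 10168 in Worker 4. Across the samples 9576 loci (61.4%) were detected in all 4, and 4954 in none. Loci with an mRNA model were detected in all 4 samples in 9176 of 14306 cases (64.1%), with a median level of 21.5 FPKM. Loci with only a noncoding RNA model were detected in all 4 in 267 of 603 cases (44.3%), at a median of 16.9 FPKM. The bulk of the detected loci, 6289, had a median level from 10 to 100 FPKM, while 834 lay from 100 to 1000 FPKM and 72 above 1000 FPKM. Annotated loci under 100 nt, tRNA entries among them, were listed at 0 in all 4 samples in 220 of 221 cases. They are shorter than the 334 to 361 nt by which the authors' quantification shortened transcripts of 1000 to 6000 nt, so their zeros say nothing of their transcription.

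The 20 most abundant annotated loci were 14 nuclear and 6 mitochondrial ones. LOC105197556, a gene of 2 exons and 452 nt on scaffold Si_gnG.scaffold03972 from 36 to 1561, had the highest median level, with 13210 FPKM in Worker 1, 11093 in Worker 2, 13691 in Worker 3 and 16300 in Worker 4. LOC105193375, a protein-coding gene of 4 exons on Si_gnG.scaffold01665 from 71182 to 73286, came next but differed 8.02-fold between samples, from 2718 FPKM in Worker 1 through 8950 in Worker 2 and 13563 in Worker 3 to 21801 in Worker 4. The locus of XM_011173132.1, on Si_gnG.scaffold08068 from 1712185 to 1729282, held 7772, 6190, 9174 and 9889 FPKM in Worker 1 to Worker 4. An unnamed mitochondrial RNA, rna22278, at 11269 to 12601 of the mitochondrial sequence, held between 5170 and 8569 FPKM. The sources used here give no type for rna22278. Of the 37 mitochondrial loci 22 are tRNA entries, and rna22278 and rna22279 are the only ones without a gene name. By elimination rna22278 is likely a ribosomal RNA, which the rule for named genes would have left out. LOC105201829 had between 5136 and 7016 FPKM in Worker 1 to Worker 3 and 12161 FPKM in Worker 4. LOC105206506 ranged from 4312 to 6483 FPKM. LOC105197517, a longer gene of 15 exons on Si_gnG.scaffold03952 from 3028499 to 3036691, stayed between 3229 and 4211 FPKM, and LOC105200532 between 3001 and 3575 FPKM, which made it the steadiest of the nuclear genes in this set with a ratio of 1.19.

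Several other loci of the abundant set varied more. LOC105199067, known only from a noncoding RNA model, was highest in Worker 1 at 7036 FPKM and between 2887 and 3775 FPKM in the other 3 samples. LOC105198998 was lowest in Worker 2 at 1063 FPKM and highest in Worker 4 at 5664 FPKM. LOC105194481 went from 758 FPKM in Worker 1 to 5547 FPKM in Worker 4, and LOC105199979 from 782 to 4138 FPKM in the same samples. LOC105203595 ranged from 2031 to 4390 FPKM, LOC105206668 from 2178 to 3068 FPKM and LOC105201391 from 1646 to 2980 FPKM. The remaining members of the 20 were the mitochondrial genes COX1, COX2, COX3, ATP6 and ATP8. LOC105203595, of 320 nt, and ATP8, of 154 nt, are shorter than the length removed from longer transcripts. In Worker 1 the bounds of ATP8 translate to 436 fragments and those of ATP6, at a similar FPKM, to 60409. The FPKM of ATP8 thus overstates its part of the reads, and its place among the 20 depends on that correction. LOC105203595 was alone in its Cufflinks gene in no sample, so how far its place depends on the correction is not known. LOC105206668 of 374 nt, LOC105199067 of 436 nt and LOC105197556 of 452 nt are not much longer than the length removed. How far the correction raised their levels was not worked out.

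**Figure D1:**
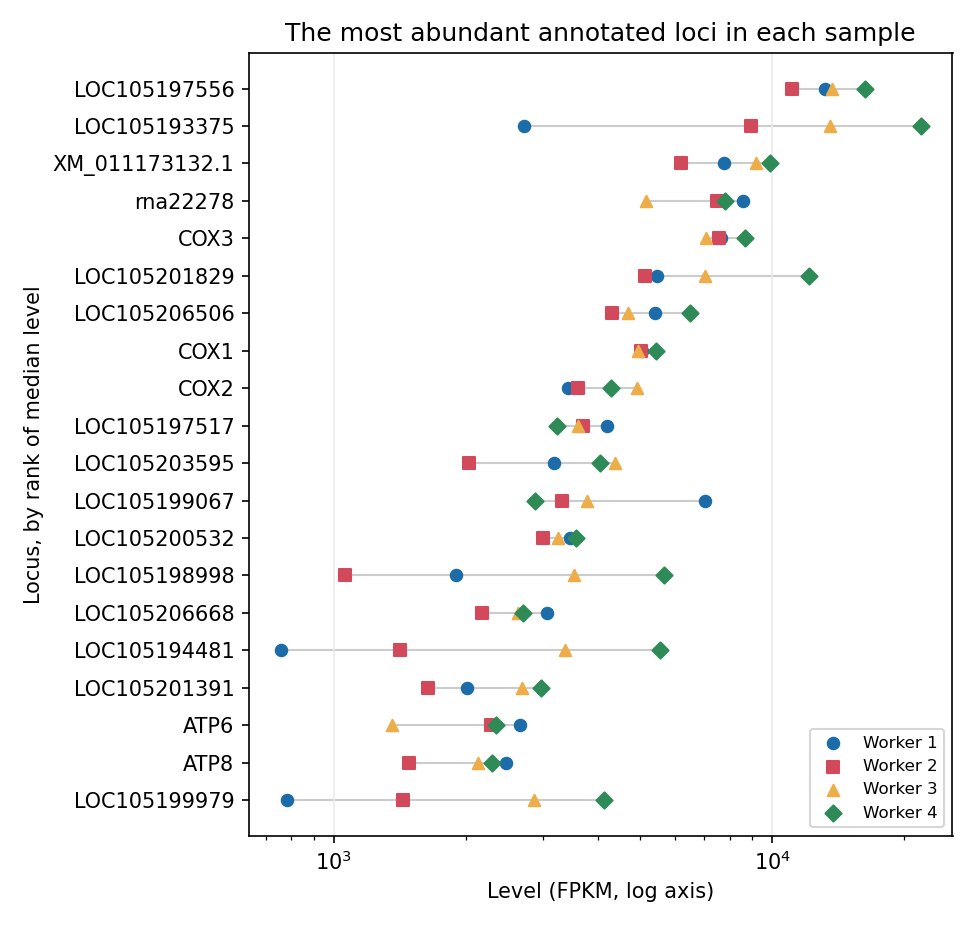
Level of the 20 annotated loci with the highest median level, in FPKM on a log axis, with 1 symbol per sample and a grey line from the lowest to the highest sample. COX1 spans only 4956 to 5430 FPKM, whereas LOC105193375 spans 2718 to 21801 FPKM.

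Mitochondrial mRNAs, which encode subunits of the respiratory chain and of ATP synthase, differed far more between genes than between samples. The cytochrome c oxidase genes were the highest, with medians over the samples of 7594 FPKM for COX3, 5041 for COX1 and 3951 for COX2. ATP6, which encodes an ATP synthase subunit, had a median of 2311 FPKM, and CYTB, which encodes cytochrome b of complex III, 1660 FPKM. ATP8, for another ATP synthase subunit, was listed at a median of 2214 FPKM, but this cannot be set level with ATP6: in Worker 1 the bounds of ATP8 translate to 436 fragments and those of ATP6 to 60409. Among the 7 genes for NADH dehydrogenase subunits, the 6 with a level above 0 had a median of 228 FPKM, from 20.8 for ND6 to 666 for ND5. COX1 was the steadiest, between 4956 and 5430 FPKM, a ratio of 1.10, and COX3 lay between 7078 and 8697 FPKM. ND1 varied most, with 278 FPKM in Worker 1, 397 in Worker 2, 88.6 in Worker 3 and 173 in Worker 4, a ratio of 4.44. The half-widths of the authors' bounds for ND1 were at most 6.61 FPKM, far less than these differences. ND3, of 351 nt, was lowest in Worker 1 at 131 FPKM. It was listed at 289 FPKM in Worker 3 and 252 in Worker 2, but its bounds translate to 1933 and 2151 fragments, so the order of these samples depends on the correction for length. ATP6 was lowest in Worker 3 at 1357 FPKM against 2280 to 2665 FPKM in the others. ND4L, from 8007 to 8294, was listed at 0 in all 4 samples although reads were marked as covering it. It overlaps ND4, from 6676 to 8013, and no level is given for it. The 22 mitochondrial tRNA entries were all listed at 0.

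**Figure D2:**
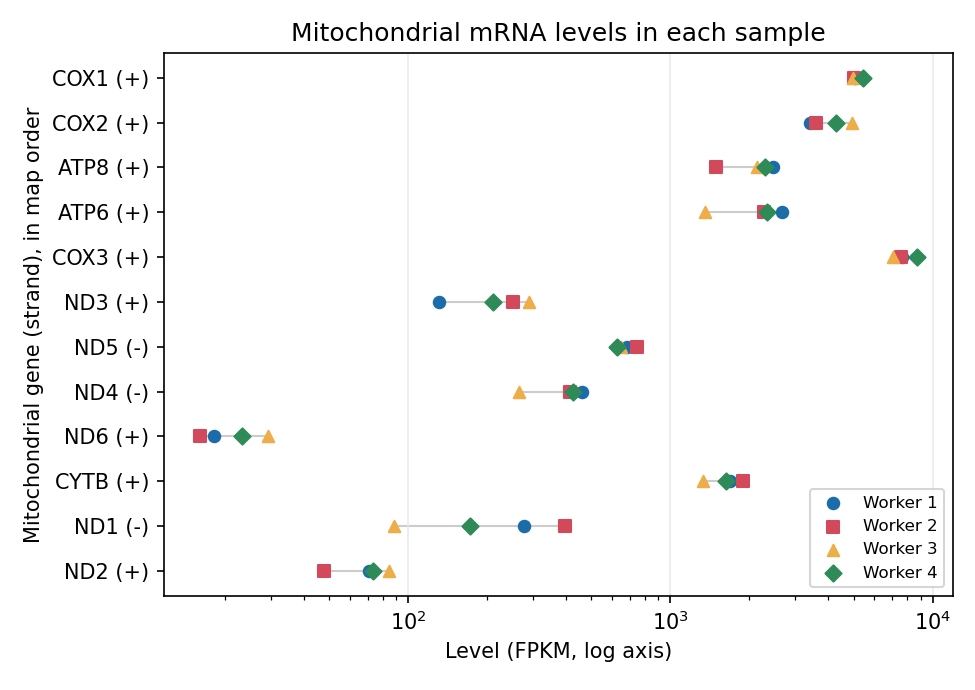
Levels of 12 mitochondrial mRNAs in map order, in FPKM on a log axis, with 1 symbol per sample, the coding strand in parentheses and a grey line from the lowest to the highest sample. COX3 holds between 7078 and 8697 FPKM and ND6 between 16.1 and 29.2 FPKM, and the widest spread is that of ND1.

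Few nuclear genes carry a name of their own in the table used here, and 7 of these could be matched to the files. GSTS1, a sigma-class glutathione S-transferase (LOC105197561, 4 exons, Si_gnG.scaffold03982 from 3663 to 5271), was abundant, with 490 FPKM in Worker 1, 568 in Worker 2, 671 in Worker 3 and 939 in Worker 4. Its median of 620 FPKM lay above 98.6% of the loci detected in all samples. An odorant-binding protein gene (LOC105195107, Si_gnG.scaffold02694 from 657033 to 658677), of the family that carries small hydrophobic ligands, held 44.9, 38.3, 21.5 and 53.4 FPKM in Worker 1 to Worker 4. The half-widths of the bounds were between 2.05 and 3.24 FPKM, so the low value of Worker 3 stood outside counting error. The insulin receptor gene InR-2 (LOC105195102, Si_gnG.scaffold02694 from 445650 to 491265) was expressed at a low level, 5.04, 7.61, 5.23 and 4.48 FPKM in the same order. CYP6A14, a cytochrome P450 gene (LOC105195645), lay between 0.0794 and 0.362 FPKM.

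The vitellogenin receptor gene VgR (LOC105200757), whose product takes up yolk protein into oocytes, lay between 0.0317 and 0.0507 FPKM, which the bounds translate to between 6.0 and 9.59 fragments per sample over 5471 nt. The antigen 5 gene (Ag5, LOC105199703), of a family found in venoms, was at 0.288, 1.23, 0.0381 and 0.0756 FPKM in Worker 1 to Worker 4, with 31.9 fragments in Worker 2 and 1.00 in Worker 3. Osi6 (LOC105198794), of the insect Osiris family, was listed at 0 in 3 samples and had 1.00 fragment in Worker 4. CYP6A14, VgR and Osi6 therefore stayed under 1 FPKM in all 4 samples.

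The 4 samples had broadly alike profiles, and Worker 2 and Worker 4 were the most distant pair. Across 10259 loci with a mean level of at least 1 FPKM, Pearson correlations on the log2 scale ran from 0.913 between Worker 2 and Worker 4 to 0.948 between Worker 3 and Worker 4, with a median of 0.936. Spearman correlations ran from 0.924 to 0.959 with a median of 0.951, for the same lowest and highest pairs. No locus above 0 had an identical value in any pair, so no file repeats another. The median absolute difference between samples of a pair was 0.34 on the log2 scale for Worker 2 and Worker 4 and between 0.19 and 0.27 for the other 5 pairs. Between Worker 2 and Worker 4, 546 loci were at least 2-fold higher in Worker 4 and 453 at least 2-fold lower.

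A minority of loci differed among the samples by a large factor, and their number depends on which transcripts are summed. The highest sample was at least 2 times the lowest at 1662 of the 10259 loci (16.2%) and at least 4 times at 441 (4.30%), and the median ratio was 1.41. Of the 441 loci, 265 were at exactly 0 in at least 1 sample, and 176 were above 0 in all 4. The authors' bounds, combined over a locus's transcripts as if independent, did not overlap between highest and lowest sample at 175 of these 176. These loci had been chosen for a 4-fold difference, so this adds little. With reference transcripts alone the counts were higher, 3076 at 2-fold and 1414 at 4-fold. Without the loci listed at 0 the 4-fold count was 176, and without Worker 4 the 2-fold count was 1008, without Worker 2 1073. Among loci with a mean of at least 5 FPKM that were above 0 in all samples, 134 differed 4-fold, and 60 of these had their lowest level in Worker 1 and their highest in Worker 4. The next most frequent order, lowest in Worker 2 and highest in Worker 4, held 13 loci.

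The 10 loci with the largest ratios were mostly loci listed at 0 in some sample. LOC105196315, on Si_gnG.scaffold03065 from 380995 to 551704 with 50 annotated transcripts, was at 952 FPKM in Worker 1, 566 in Worker 2 and 121 in Worker 3 and was listed at 0 in Worker 4. By the mean depth over its exons it held 44.5, 24.3, 5.08 and 0.643 in the same order. LOC105200382 was listed at 0 in Worker 1 and Worker 2 and stood at 223 and 294 FPKM in Worker 3 and Worker 4, with a ratio of 5.10 by mean depth. LOC105195453 was listed at 0 in Worker 2 against 167 to 253 FPKM elsewhere, and LOC105200034 at 0 in Worker 2 against 71.7 to 87.0 FPKM, and both stayed at 0 there by mean depth. LOC105201583 was listed at 0 in Worker 3 against 144 to 165 FPKM, and LOC105204832 at 0 in Worker 4 against 64.8 to 123 FPKM. By mean depth these held 29.2 and 13.1 in the same samples, and their ratios were 4.998 and 6.01. LOC105199100, at 70.6 to 87.1 FPKM elsewhere, has no entry in the file of Worker 2 and is counted as 0 there, but by mean depth Worker 2 held 59.5. The locus of XM_011175287.1 was above 0 in Worker 1 alone, at 89.7 FPKM. LOC105195170 stood at 947 FPKM in Worker 2 against 6.22 to 6.47 FPKM elsewhere, but at 3.38 by mean depth in Worker 2. Nearly all of the 947 FPKM thus came from assembled transcripts of the same Cufflinks gene that hardly overlap its exons. It is not a level of the annotated gene. The locus of XR_851179.1, a noncoding model on Si_gnG.scaffold07705 from 50364 to 51113, was at 229 FPKM in Worker 3 against 1.45 to 2.16 FPKM elsewhere, with the same values by mean depth.

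Each sample also had loci that set it apart from all others. Worker 4 had the most loci at least 2-fold above every other sample, 60, and Worker 1 the fewest, 16, with 32 in Worker 2 and 23 in Worker 3. Loci at least 2-fold below every other sample numbered 66 in Worker 1, 64 in Worker 2, 41 in Worker 3 and 39 in Worker 4, of which 19, 42, 20 and 16 were listed at 0. Besides XM_011175287.1, the farthest loci of Worker 1 were LOC105195826 at 37.7 FPKM with 0 elsewhere, and XR_851156.1, LOC105203210 and XM_011157716.1, listed at 0 against at least 26.2, 20.5 and 18.8 FPKM elsewhere. Worker 2 was farthest at LOC105195453, LOC105195170, LOC105200034, LOC105199100 and LOC105195735, the last listed at 0 against 55.4 to 60.8 FPKM. At LOC105195170 Worker 2 was highest by the summed level alone, and not by mean depth. Worker 3 was farthest at LOC105201583 and XR_851179.1, at XM_011166418.1 and XR_851509.1, listed at 0 against at least 57.1 and 48.0 FPKM, and at XR_850869.1, at 43.5 FPKM with 0 elsewhere. Worker 4 was farthest at LOC105196315 and LOC105204832 and at 3 loci with 0 elsewhere, XM_011161462.1 at 73.9 FPKM, XM_011163803.1 at 69.4 FPKM and LOC105199392 at 64.8 FPKM. Of the 12 named loci in which the sample set apart was itself at 0, 9 were marked in its file as fully supported by reads. By mean depth 3 of these 9 held at least 1 in that sample and 5 stayed at 0, so neither value settles whether the transcripts were absent there.

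Worker 2 and Worker 4 differed from the other samples in opposite ways according to transcript length. Over 8426 nuclear loci with a mean of at least 5 FPKM and no zero, the deviation of a sample from the locus's median rose with transcript length in Worker 2, with a Spearman rho of 0.406, and fell in Worker 4, with a rho of -0.404, across loci. It was 0.156 in Worker 1 and -0.124 in Worker 3. Loci with transcripts over 8000 nt had a median deviation of 0.27 in Worker 2 and -0.34 in Worker 4 on the log2 scale, and loci from 500 to 1000 nt -0.23 and 0.08.

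**Figure D3:**
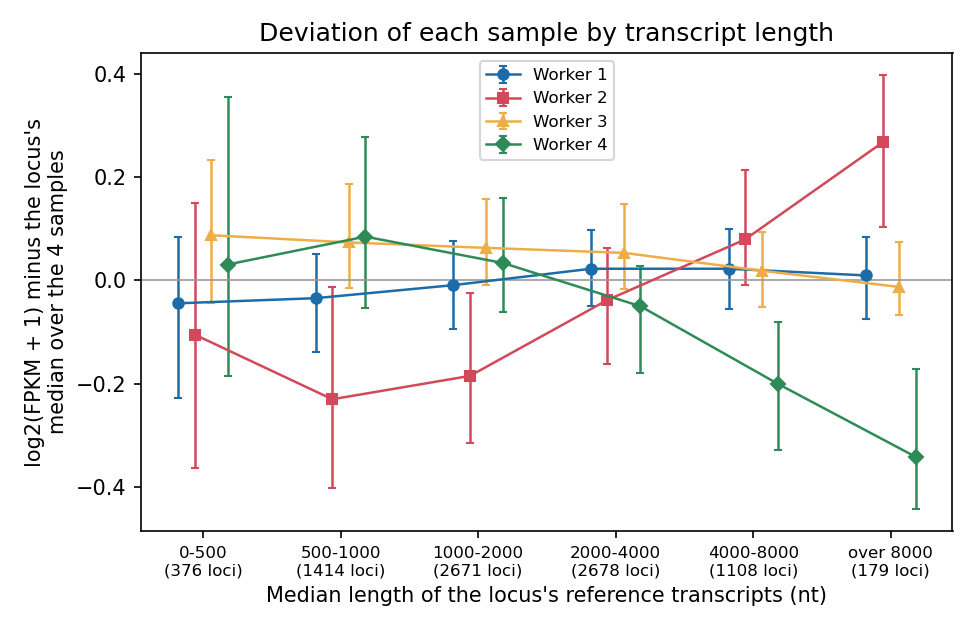
Deviation of each sample from the median of the 4 samples on the log2(FPKM + 1) scale, in 6 bins of transcript length; points are medians over loci and bars span the lower to the upper quartile. The medians of Worker 2 and Worker 4 cross with length. They are -0.10 and 0.03 under 500 nt, -0.23 and 0.08 from 500 to 1000 nt, and -0.04 and -0.05 from 2000 to 4000 nt. Above 8000 nt they reach 0.27 and -0.34. Worker 1 and Worker 3 stay between -0.04 and 0.09.

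The 10 highest annotated loci took these shares of the summed annotated level: 11.7% in Worker 1, 11.9% in Worker 2, 11.7% in Worker 3 and 14.1% in Worker 4. Mitochondrial loci together held 5.73%, 5.90%, 4.46% and 4.82%, and their mRNAs alone between 3.65% and 4.49%. The order of the samples depends on the loci counted. With unannotated loci included, the 10 highest held 34.7%, 17.4%, 24.7% and 12.7% in Worker 1 to Worker 4, and mitochondrial loci 2.23%, 3.13%, 2.54% and 3.45%. Loci with only noncoding models held between 4.00% and 4.54% of the annotated level. No nuclear locus of the files is named as ribosomal RNA in the sources used here, so its share is not given.

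Many assembled transcripts lay outside the annotated loci, mostly as single unspliced pieces at low levels. Worker 1 had 9234 unannotated loci, Worker 2 9840, Worker 3 9652 and Worker 4 9264, with a median transcript level between 3.17 and 3.68 FPKM and a median length between 653 and 672 nt. Spliced ones numbered 804, 832, 889 and 859. Joined across samples they made 12604 loci, of which 5111 were assembled in all 4 samples and 3910 in 1 sample alone. Of the 12604, 322 (2.55%) overlapped an annotated exon, 2919 (23.2%) lay within an annotated intron, 2207 (17.5%) within 1000 nt of an annotated locus and 7156 (56.8%) farther away. The summed level of unannotated transcripts was 61.1% of all FPKM in Worker 1, 47.0% in Worker 2, 43.2% in Worker 3 and 28.4% in Worker 4. With transcripts under 200 nt left out it was 17.5%, 17.1%, 16.3% and 13.8%.

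Very short pieces made most of the difference between these shares. Pieces under 150 nt numbered 92, 94, 69 and 60 in Worker 1 to Worker 4 and held 50.2%, 31.0%, 28.0% and 13.5% of the summed FPKM. They rested on 2408, 1929, 1621 and 1369 fragments, at most 0.00709% of a sample's fragments. In a piece of 125 nt a single fragment was worth 1251 FPKM in Worker 1, 5313 times what its printed length alone would give. The highest FPKM of Worker 1, 276712, belonged to such a piece of 126 nt on Si_gnG.scaffold05494 from 16699 to 16824, with 366 fragments.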

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

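Of 74 alternative values computed for 10 results, 53 stayed within their limits and 21 moved. Settings chosen only after the data were examined were reference transcripts alone, mean depth, transcripts or loci under 200 nt left out, loci listed at 0 left out and the length trend removed. Mean depth was run for the counts of detected loci, the correlations and the 2-fold and 4-fold counts, and none of these moved. The length trend was removed for the 2-fold and 4-fold counts alone, and neither moved. Counts of detected loci stayed within 1.5 times of the main count under every setting tried. The median Pearson correlation was 0.888 with a pseudocount of 0.1, 0.976 without a filter, 0.832 with reference transcripts alone and 0.967 without loci listed at 0. The median Spearman correlation was 0.965 without a filter, 0.936 with the most abundant transcript, 0.870 with reference transcripts alone and 0.965 without loci listed at 0. The number of 2-fold loci was 3076 with reference transcripts alone and ran from 1008 to 1403 when 1 sample was left out, the lowest without Worker 4. The number of 4-fold loci was 283 at a mean of at least 5 FPKM, 1414 with reference transcripts alone and 176 without loci listed at 0, and 337 of the 441 were also 4-fold by mean depth. The share of the 10 highest loci, at a median of 11.8%, was 24.1% for the 50 highest and 21.0% over all loci. The mitochondrial share, at a median of 5.28%, was 2.84% over all loci and 4.15% over all loci of at least 200 nt. The median number of unannotated loci, 9458, was 846 for spliced ones, and their share of 45.1% was 3.22% for spliced ones and 16.7% without transcripts under 200 nt. The cause of these moves was not tested, except that short pieces, leaving out of loci and narrower sets act by construction. Alternatives for gene list levels and list shifts were not run, since no list could be formed. No paired analysis was possible because the samples belong to no groups.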

Other observations

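Splicing outside the annotation was partly shared by the samples. Assembled transcripts in annotated loci had 13240 different intron chains that no reference transcript has, and 443 of these, in 430 loci, were assembled in all 4 samples, against 10220 in a single sample. Of the 443 shared chains, 324 used at least 1 splice junction outside the annotation and 119 combined annotated junctions. LOC105203595 is an example: annotated as a single exon from 525547 to 525866 of Si_gnG.scaffold07703, it was joined in all 4 samples to an upstream exon across an intron from 524961 to 525546, at 379, 227, 611 and 549 FPKM in Worker 1 to Worker 4. Among 2960 loci with at least 2 annotated intron chains that were detected in all samples, 2079 (70.2%) had the same leading annotated chain in every sample.

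Of the unannotated loci, 373 had an identical intron chain in all 4 samples, and 313 of these lay farther than 1000 nt from any annotated locus. The median level of the 373 was 12.6 FPKM, and 160 of the 373 held at least 10 FPKM in every sample. The most abundant of at least 500 nt lay on Si_gnG.scaffold06774 from 417388 to 418497, with 2 introns, at 5068 FPKM in Worker 1, 1835 in Worker 2, 6640 in Worker 3 and 1970 in Worker 4. A spliced locus on Si_gnG.scaffold01962 from 1827643 to 1834654 held 201, 529, 1300 and 1018 FPKM in the same order. Both of these loci lay within 1000 nt of an annotated locus, as did 25 of the 373. At the 2-fold limit 46.9% of the 373 differed among the samples.

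In the patterns weighed next, the tests of unspliced RNA, of the length trend as a source of the gene set and of a single added source of RNA were set before their results were seen, and the other tests, the position of Worker 2 among them, afterwards. The labels name no condition, so no biological explanation was tested.

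Among 8575 nuclear loci with a mean of at least 5 FPKM, 149 were at 0 in at least 1 sample, 210 zeros in all, with the most, 72, in Worker 2. A lack of reads is argued against as the source of them all, since 73.3% of the zeros (154) carry the mark of full read support in the same file, as do 88.3% of the values at loci without a zero but only 8.18% of those at the 1952 nuclear loci at 0 in all 4 samples. At zeros of loci without exon overlap the share was 66.4%. The mean depth over the exons was 0 at 170 of the zeros and at least 1 at 30, but it is built from the same FPKM values, so it cannot show whether reads were lacking. For the 56 zeros without the mark a lack of reads stays open. Exons of another annotated locus overlapped 31.5% of these loci and 12.1% of the others, an odds ratio of 3.34 (95% interval 2.30 to 4.79, two-sided Fisher's exact p = 5.65e-10, across loci, which are not independent). Only overlap between strands could be counted, because loci with exon overlap on 1 strand had been joined. This is consistent with estimates that may fail where loci overlap, although most of the 149 loci have no such overlap and their zeros stay open.

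The trend with transcript length in Worker 2 and Worker 4 was not a matter of short transcripts: above 2000 nt rho was 0.415 and -0.381, so even the smaller in size, 0.381, stood far from 0. Expression level alone is argued against as well, since rho kept its sign in each of 5 bins of mean level and its smallest size there was 0.270. Unspliced RNA would follow a gene's span in the genome, but transcript length held the larger partial rho in both samples, by 0.0993 ± 0.0200 (bootstrap SE) in Worker 2 and 0.201 ± 0.0244 in Worker 4. Given length, span still held a partial rho of 0.121 in Worker 2 and -0.0580 in Worker 4. Span and length were themselves correlated at 0.714. The trend thus followed length more than span, but a part from unspliced RNA is not excluded. Differences in RNA integrity, fragmentation or size selection, and a real shift between long and short messages, stay open and were not tested.

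Of 134 loci that differed 4-fold without a zero at a mean of at least 5 FPKM, 60 were lowest in Worker 1 and highest in Worker 4, where 11.2 would be found if the 12 possible orders were equally frequent. This order was picked as the most frequent, and loci that vary together need not fill the orders equally, so 11.2 is no test of it. LOC105193375, LOC105194481, LOC105199979, LOC105207450 and LOC105202373 are the most abundant of the 60. The set's median level was 18.1 FPKM in Worker 1, 39.98 in Worker 2, 75.2 in Worker 3 and 135 in Worker 4. These loci are short, with a median transcript length of 731.5 nt against 1873.5 nt for nuclear loci with a mean of at least 5 FPKM, and short loci are slightly higher in Worker 4. The length trend is argued against as the whole cause by its size. Loci from 500 to 1000 nt deviated by a median of -0.03 in Worker 1 and 0.08 in Worker 4 on the log2 scale. Once the trend was removed, 90.0% (54) kept the order and the 4-fold difference. So small a shift could take out little more than loci near the 4-fold limit, so this share adds no further evidence. Why the set is short stays open. Some of its loci are shorter than the length removed from longer transcripts. LOC105206726 of 214 nt, XR_851381.1 of 252 nt, LOC105206282 of 280 nt and XR_850781.1 of 324 nt are among them. How far the correction for length raised their levels was not worked out. By mean depth, which counts all transcripts over the exons, 85.0% (51) kept the order and the 4-fold difference. The choice of transcripts summed for a locus therefore does not make the pattern at these 51. The mean depth is built from the same FPKM values, so it cannot show whether fragments were wrongly split among overlapping transcripts, and this stays open. A single added source of RNA in graded amounts, such as tissue carried along in dissection, could give this order and would put Worker 3 at the same point between Worker 1 and Worker 4 for every locus, and likewise Worker 2. The interquartile range of that position was 0.153 (bootstrap interval 0.110 to 0.244) around a median of 0.447 in Worker 3 and 0.164 (0.114 to 0.240) around 0.186 in Worker 2, and both intervals straddle the limit of 0.2 set for Worker 3. Single loci lay from 0.0120 to 0.986 in Worker 3 and from 0.00446 to 0.729 in Worker 2, and Worker 2 was below Worker 3 at 52 of the 60 loci, not at all. How far single loci scatter without such a source is not known from 4 samples, and so this source and a set of genes that vary together cannot be told apart.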
